A study of Mus musculus with 2 samples.

How the data were processed

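Single-cell suspensions of total testicular cells from adult wild-type mice and from mice lacking miR-202 were run on a droplet platform with 3′ chemistry, with 1 library per genotype. Per the labels' protocols, debris was removed by sorting before loading. The deposited table holds UMI counts per gene and barcode, as whole numbers that were not normalised, per the values themselves. The submitters' processing notes name Cell Ranger 1.3.1, Seurat 3.2.2 and the mouse build GRCm38. The filter that the authors put on the deposited barcodes is not given in the sources used here. In the table no barcode had fewer than 3529 UMIs or 1280 genes, and the highest mitochondrial share was 20.0% under each mark.

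The 20476 genes and 28245 barcodes are joined in 1 table, in which the end of each barcode name, 1 or 2, was read as the mark of a library. The labels do not state this, and no source used here ties a mark to a genotype. Marks were not assigned from sample order or from counts. The planned comparisons of knockout with wild type, over classes, lists and miR-202 seed sites, were therefore not made. They were replaced, after the table had been seen, by levels in each germ class and by comparisons of each germ class with the one before it, made under each mark. The mature order of the classes is textbook knowledge and was not estimated from the data. The classes come from clusters of the same counts, so that differences between classes are partly set by the clustering.

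Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which left out none. Counts were scaled to 10000 per barcode and log-transformed, 2000 variable genes were chosen, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave the clusters. Scrublet was run on each library with an expected doublet share of 10%. It called 3 of 12935 barcodes (0.0232%) under mark 1 and 386 of 15310 (2.52%) under mark 2. A share below 0.5% was taken to mean that the caller had not worked, so all barcodes were kept, and the shares without the calls are an alternative. Doublets therefore remain in the classes.

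Cell type markers, gene lists, filters, the size rule and the other settings to be tried were fixed before the data were examined. The rule that names clusters from the markers was not. A first rule, by mean z-score of the markers, was set aside after its clusters had been seen. In the rule used, a marker was up in a cluster if its CPM plus 10 was at least 2 times the mean over clusters plus 10. A cluster took the name of the class with the largest share of markers up, if at least 3 were up and no other class with at least 3 up had more than 0.5 of that share. A cluster that raised early and late spermatocyte markers was called mixed, and other unresolved clusters were clustered again at resolution 0.5. Clusters whose own markers were outnumbered by those of another class among the 10 leading genes stayed unnamed. The results under the first rule are given as an alternative.

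UMIs were summed over the barcodes of each class under each mark and divided by the class total to give CPM. A gene was called higher or lower between classes if its CPM differed at least 1.5-fold in the same direction under both marks, with at least 50 CPM and 50 UMIs in the class where it was higher. A gene counted as measured with at least 20 UMIs over the classes compared. A gene with 0 UMIs was set at a floor of 3 counts. Ratios have exact conditional binomial 95% intervals, shares have Clopper-Pearson intervals and levels have exact Poisson intervals. With 1 pool of cells no test was run, and the calls describe these libraries. Markers that named the classes were left out of the counts, which leaves 344 of 436 listed genes in 23 lists. Depth per barcode was compared after thinning each cell to 1000 UMIs.

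Genes were named by a rule: Espl1, Rec8, Stra8 and Dmrtb1 in every germ class, and for each list described 2 to 4 members of the largest absolute log2 ratio and at least 50 CPM. The latter part was not kept throughout: members that did not pass the size rule were mostly left out, some named members have a smaller ratio than others left unnamed, and some lists are described by counts or by 1 gene. A further part of the rule, the 5 highest and 5 lowest genes of each genotype comparison, was not used. Lists were chosen for description by their counts and by the place of their median among 10000 random lists of like expression, a choice made after the values were seen. Genes named outside the rule, such as the somatic markers, Dpy19l2, Zpbp2, and genes in the observations that follow the report, were also chosen after their values were seen.

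Symbols were matched to the GENCODE M21 annotation of GRCm38, which gave a position for 20088 of 20476 genes (98.1%), 693 of them X-linked. Free RNA was estimated from the profile of 6 unnamed clusters of low UMI count, scaled so that it used up the Prm1, Prm2, Tnp1 and Tnp2 UMIs of the spermatogonium-like and spermatocyte-like classes. For the spermatid-like classes, which may make these transcripts, the mean of those 4 estimates was used. This estimate assumes that the earlier classes make none of them and that the 6 clusters hold free RNA alone, and barcodes rich in protamine UMIs raise it. The latter is in doubt for the cluster led by Pou5f2 and for clusters with mitochondrial genes among their leading genes, so the estimate was repeated with the clusters led by Gm8251 and AY036118.

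Alternatives were other cell filters, doublet treatments, cluster resolutions, numbers of components and centring within a library for the shares. For the class comparisons they were scaling by a median ratio or by TMM factors, mean CPM per cell, other filters and ratios, and thinned counts. Classes from resolution 2 and classes without the called doublets were also used. The median ratio was taken over the genes with at least 50 UMIs in both classes under the mark. Alternatives added after the data had been seen were 1 doublet threshold for both libraries, clustering without the listed genes, the first naming rule, leaving out the low-UMI cluster of the round spermatid-like class, and subtracting the free-RNA profile of the 6 or of the 2 clusters. The size rule was tested on simulated data for the 20476 genes, with 200 genes changed 2-fold or 3-fold in each comparison. It recovered 98% to 100% of them and called 0 unchanged genes. Both simulated changes exceed the 1.5-fold of the rule, and the changed genes were drawn from those at 2 or more times its 50 CPM before the change. Recovery of smaller changes, and of genes at lower levels, is therefore not shown. These values do not give the error of calls between the real classes. Those classes come from clusters of the same counts and may hold free RNA. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5 with its Scrublet, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. TMM factors came from edgeR 4.0.16 in R 4.3.3, which was used for scaling alone.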

Results

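Total testicular cells of adult mice were profiled by droplet-based single-cell RNA sequencing, with 1 library from wild-type mice and 1 library from mice lacking miR-202, a microRNA of the gonads. The stated question was how cellular composition and gene expression differ between the genotypes. The deposited table joins the libraries, and each barcode name ends in a mark, 1 or 2. Neither the labels nor the table ties a mark to a genotype, so no value below is assigned to wild type or knockout and no genotype comparison was made. The table was treated as 1 pool of testicular cells, with values given under each mark. The marks are not replicates of a group, and nothing here was tested.

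Mark 1 held 12935 barcodes and 158740437 unique molecular identifiers (UMIs), with a median of 6061 UMIs per barcode and a range of 3924 to 188645. Mark 2 held 15310 barcodes and 168967776 UMIs, with a median of 5509 and a range of 3529 to 244157. The median number of detected genes per barcode was 2470 under mark 1 and 2328 under mark 2, out of 20476 genes in the table. Intervals in brackets are exact 95% intervals, binomial for shares and ratios and Poisson for levels. They cover counting error only.

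Spermatids were the most abundant of the named cells. Elongating spermatid-like barcodes made up 23.8% of the 28245 barcodes (23.3 to 24.3%), and round spermatid-like barcodes made up 15.9% (15.5 to 16.3%). Of the 4495 round spermatid-like barcodes 1668 lay in a cluster of low UMI count, and the other 2827 made up 10.01% of the pool (9.66 to 10.4%). Earlier germ cells were scarcer. Spermatogonium-like barcodes made up 1.17% (1.046 to 1.301%), early spermatocyte-like barcodes 1.13% (1.01 to 1.26%) and late spermatocyte-like barcodes 1.29% (1.16 to 1.43%). A further 2.87% (2.68 to 3.07%) formed a mixed spermatocyte-like class, a cluster that raised markers of both the early and the late spermatocyte and had Piwil1 and Tex101 among its leading genes. Sertoli cell-like barcodes made up 4.86% (4.61 to 5.11%). Leydig cell-like barcodes made up 0.510%, T or NK cell-like barcodes 0.379%, macrophage-like barcodes 0.322% and erythroid cell-like barcodes 0.120%.

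The germ cell shares under each mark were as follows. Spermatogonium-like barcodes made up 1.23% under mark 1 (1.05 to 1.43%) and 1.12% under mark 2 (0.957 to 1.296%). For the early spermatocyte-like class the values were 1.35% (1.15 to 1.56%) and 0.947% (0.800 to 1.11%), and for the mixed class 3.11% (2.82 to 3.42%) and 2.67% (2.42 to 2.94%). Late spermatocyte-like barcodes made up 1.64% under mark 1 (1.43 to 1.87%) and 0.993% under mark 2 (0.842 to 1.16%). Round spermatid-like barcodes made up 15.2% and 16.5%, elongating spermatid-like barcodes 23.2% and 24.3%, and Sertoli cell-like barcodes 5.23% and 4.55%. Among the named classes, median UMIs per barcode under marks 1 and 2 ranged from 4985 and 4305 in Sertoli cell-like cells to 43880 and 34860 in the mixed spermatocyte-like class. With each cell thinned to 1000 UMIs, elongating spermatid-like cells had a median of 557 and 554 detected genes, against 743 to 783 in the spermatogonium-like and spermatocyte-like classes and 760 and 759 in round spermatid-like cells.

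**Figure D1:**
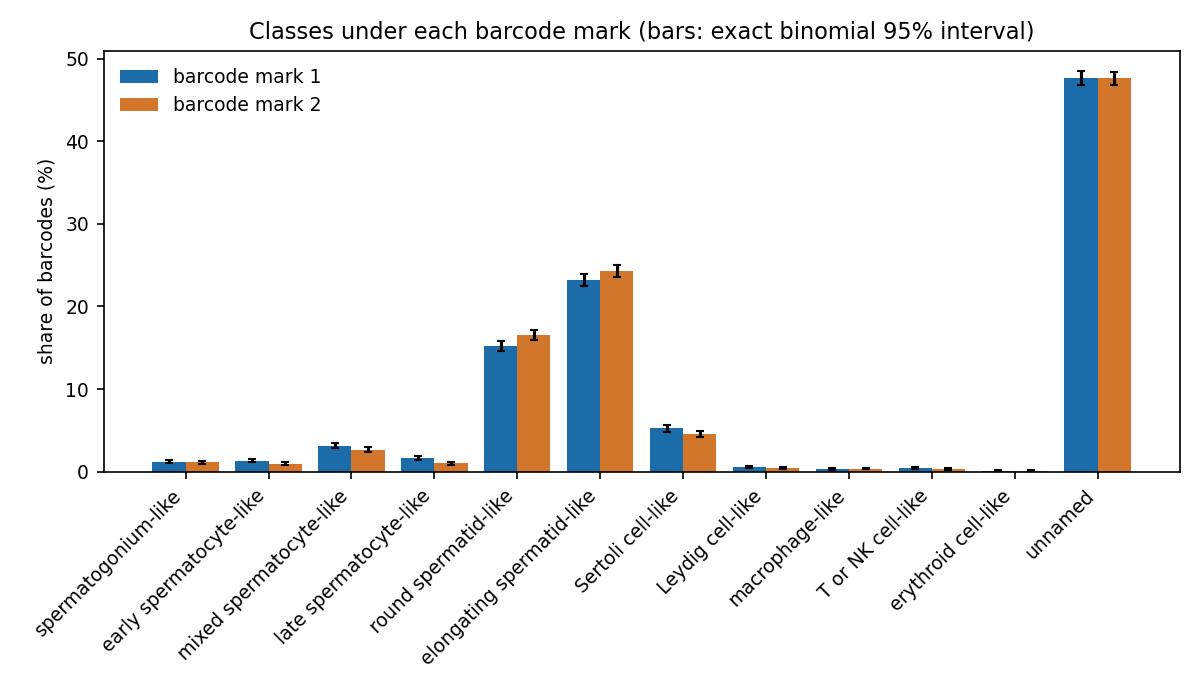
Share of barcodes in each class under barcode mark 1 (blue) and mark 2 (orange), in percent, with exact binomial 95% intervals as bars. Elongating spermatid-like barcodes make up 23.2% and 24.3%, and barcodes without a class name 47.7% and 47.6%.

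Barcodes without a class name made up 47.6% of the pool. Most of them lay in 6 clusters of low UMI count, which held 44.1% of all barcodes (42.9% under mark 1 and 45.1% under mark 2) at a median of 4472 UMIs and raised fewer than 3 markers of any class. Their first leading genes were Ttn, Pou5f2, Gm8251, AY036118, mt-Nd2 and Gm35256. The cluster led by Pou5f2 held 6.52% of barcodes under mark 1 (6.10 to 6.96%) and 11.2% under mark 2 (10.7 to 11.7%). The others lay closer between the marks, most of them higher under mark 1. Another unnamed cluster, of 482 and 281 barcodes under marks 1 and 2, raised 10 of 23 round spermatid markers but had Fam71b, a marker of the elongating spermatid, among its leading genes. It held 3.73% (3.41 to 4.07%) and 1.84% (1.63 to 2.06%) of barcodes and is in neither spermatid-like share. A smaller one, of 66 and 47 barcodes, raised 12 of 25 early spermatocyte and 9 of 21 spermatogonium markers, with Cenpa and Mki67 among its leading genes. It entered neither of these 2 classes, and so neither their shares nor their comparison. Small clusters led by the stromal genes Dcn, Gsn and Mgp (46 and 34 barcodes) and by Igkc and Ighm (20 and 24 barcodes) raised markers of more than 1 class, in the latter 9 of 9 endothelial and 10 of 12 macrophage markers. Igkc had 0 UMIs under mark 2. The round spermatid-like class joined 3 clusters, and 2 of them raised no more than 3 of the 23 markers. For 1 of these, the low-UMI cluster led by Gm48051 and Ttn, the medians of 4542 and 4032 UMIs were like those of the unnamed clusters and no marker of the class was among its leading genes, so its name is weakly held. According to the labels, debris had been removed by sorting, which can set these shares. Clustering at resolution 0.5 left no late spermatocyte-like class, and with 15 principal components there was no T or NK cell-like class and the erythroid cell-like share was 5.86%. Over all settings the spermatogonium-like share lay between 0.736% and 1.57%, the early spermatocyte-like share between 1.13% and 2.30%, the late spermatocyte-like share reached 3.31% and the round spermatid-like share lay between 9.97% and 20.6%.

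Transcripts of X-linked genes were scarce in the mixed and late spermatocyte-like classes and frequent on either side of them. The sex chromosomes are known to be silenced in pachytene spermatocytes. The 693 X-linked genes supplied 1.53% of the UMIs of spermatogonium-like cells and 1.54% of those of early spermatocyte-like cells. Their share was 0.156% (0.154 to 0.157%) in the mixed class and 0.243% (0.240 to 0.245%) in late spermatocyte-like cells. It was 1.05% in round spermatid-like cells, 1.36% in elongating spermatid-like cells, 1.48% in Sertoli cell-like cells and 1.61% in Leydig cell-like cells. The share of the mixed class was 0.133% under mark 1 and 0.184% under mark 2, and that of the late class 0.276% and 0.199%. Without the 5 X-linked genes with the most UMIs (Akap4, Tsga8, BC061195, Hypm and 1700010D01Rik) the share of the elongating class was 0.937% and that of the mixed class 0.118%. Free RNA, estimated from the protamine and transition protein UMIs, made up 13.4% and 19.7% of the UMIs of the mixed class under marks 1 and 2. That is 6448.5 and 7673.1 UMIs per barcode, above the median of 4472 in the clusters that gave the profile, so it may be too high. How many of the X-linked UMIs of this class came from free RNA was not tested. The estimate rests on 6 unnamed clusters, some of which may hold more than free RNA, and from 2 of them alone, led by Gm8251 and AY036118, it was 10.9% and 15.6%.

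**Figure D2:**
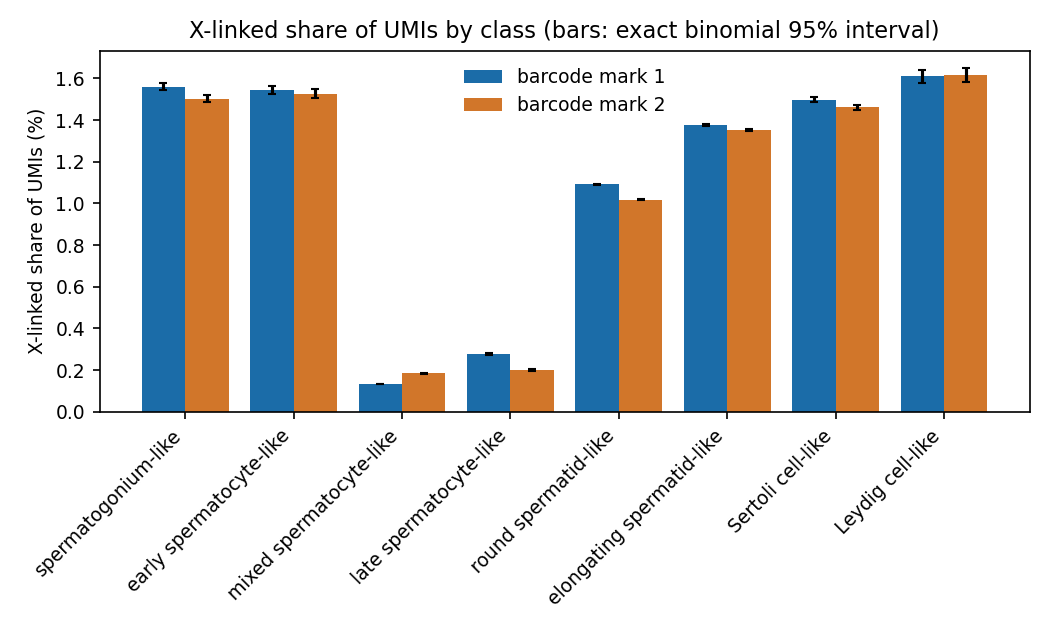
Percent of UMIs from X-linked genes in 8 classes under barcode mark 1 (blue) and mark 2 (orange), with exact binomial 95% intervals as bars. The mixed and late spermatocyte-like classes lie between 0.133% and 0.276%, and the other classes between 1.02% and 1.62%.

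Of the 4 genes fixed for every class, Stra8 was highest in early spermatocyte-like cells. Espl1 was highest in spermatogonium-like cells under mark 1 and in late spermatocyte-like cells under mark 2. Stra8 (chromosome 6, 34920163 to 34939344, forward strand, GRCm38), which is needed for entry into meiosis, stood at 188 and 190 CPM (UMIs scaled to a common class total) in spermatogonium-like cells under marks 1 and 2. It stood at 334 (306 to 364) and 432 (397 to 470) CPM in early spermatocyte-like cells and at 0.360 and 0.126 CPM in the mixed class. Espl1 (chromosome 15, 102296266 to 102324357, forward strand) encodes separase, the protease that opens cohesin rings. Its level was 52.8 (43.6 to 63.5) and 44.2 (36.0 to 53.7) CPM in spermatogonium-like cells, 39.9 and 32.7 CPM in early spermatocyte-like cells, 37.6 and 32.9 CPM in the mixed class and 52.0 and 53.4 CPM in late spermatocyte-like cells. It was 17.1 and 16.0 CPM in round spermatid-like cells, near the 19.9 (15.9 to 24.6) and 13.2 (9.86 to 17.4) CPM of Sertoli cell-like cells.

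Rec8 (chromosome 14, 55618037 to 55625395, forward strand), the meiotic kleisin of cohesin, was highest in round spermatid-like cells, at 66.4 (63.9 to 69.0) and 66.3 (64.1 to 68.6) CPM. In early spermatocyte-like cells it stood at 31.8 (23.7 to 41.8) and 28.0 (19.6 to 38.8) CPM, against 18.7 (14.8 to 23.3) and 24.9 (20.2 to 30.4) CPM in Sertoli cell-like cells, which should lack it. Dmrtb1 (chromosome 4, 107676290 to 107684230, reverse strand), a transcription factor of spermatogonia, was highest in late spermatocyte-like cells, at 903 and 985 CPM. Its level in spermatogonium-like cells, 214 and 265 CPM, was below the 399 and 392 CPM of Sertoli cell-like cells. These classes differ in depth, at medians of 12784 and 11403 UMIs per barcode against 4985 and 4305. Free RNA adds UMIs per barcode, so CPM cannot tell how much of the Dmrtb1 level is background. Dmrtb1 had 461 and 611 UMIs over 159 and 171 spermatogonium-like barcodes, and 1683 and 1512 over 676 and 696 Sertoli cell-like barcodes. Per barcode the former was only somewhat higher, so background could supply much of it. The same limit of CPM holds for Espl1 and Rec8 beside Sertoli cell-like cells. Espl1 had 673 and 821 UMIs over 1964 and 2531 round spermatid-like barcodes, more per barcode than its 84 and 51 UMIs in Sertoli cell-like cells. Stra8, Rec8 and Dmrtb1 were among the markers that named the classes, so their levels are not independent of those names.

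**Figure D3:**
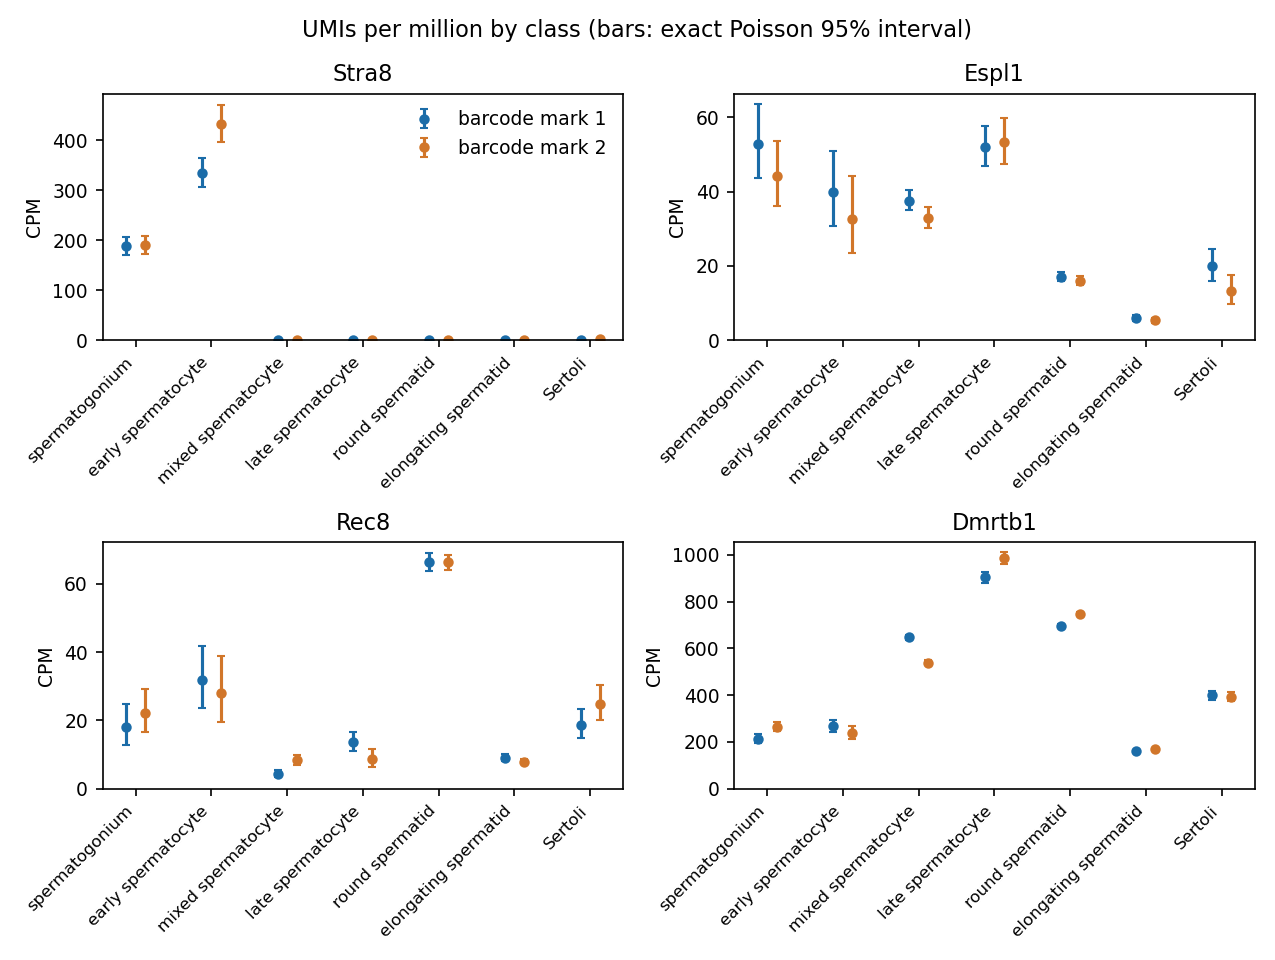
Level (CPM) of Stra8, Espl1, Rec8 and Dmrtb1 in 6 germ cell classes and in Sertoli cell-like cells under barcode mark 1 (blue) and mark 2 (orange), with exact Poisson 95% intervals as bars. Each panel has its own axis from 0, and Rec8 reaches 66.4 and 66.3 CPM in round spermatid-like cells.

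Early spermatocyte-like cells had more transcript of some genes of meiotic prophase than spermatogonium-like cells, and less of some genes of DNA replication and cell division. Of 25 measured recombination genes 7 were higher and 0 lower. Hfm1, a helicase of crossover formation, was 22.2-fold higher under mark 1 (12.4 to 43.7) and 12.6-fold higher under mark 2 (7.83 to 21.2), rising from 5.56 and 8.67 CPM to 123 and 109 CPM. Msh5, a MutS homologue of crossover sites, was 9.86-fold and 7.27-fold higher. Among 15 regulators of pachytene and the XY body 5 were higher and 0 lower, including the kinase Atr (3.82-fold, 3.26 to 4.50, and 4.83-fold, 4.04 to 5.80) and Mdc1, which binds phosphorylated H2AX (4.68-fold and 3.28-fold). Of 9 genes of telomeres and the nuclear envelope in prophase 3 were higher, among them Terb1, which links telomeres to the envelope (5.35-fold and 7.31-fold), and the lamin gene Lmnb1 was lower, at a ratio of 0.361 and 0.177. Genes of the synaptonemal complex went both ways, with 1 of 6 higher (4930447C04Rik, 5.64-fold and 5.61-fold) and Trip13 lower, at 0.430 and 0.467. With free RNA subtracted 3 were higher, or 4 with the profile of 2 clusters, and 1 was lower. The median of this list lay at percentiles 98.0 and 97.6 of random lists.

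Of 8 genes of meiotic initiation 3 were higher in early spermatocyte-like cells, with Meioc at 5.36-fold (4.42 to 6.53) and 6.09-fold (4.97 to 7.50) and its partner Ythdc2 at 2.80-fold and 2.81-fold. Cohesin genes went both ways, with 2 of 20 higher (4 with free RNA subtracted) and 2 lower: the loader Nipbl was 3.13-fold and 2.56-fold higher, Stag3 2.34-fold and 2.24-fold higher, and the mitotic kleisin Rad21 lower, at a ratio of 0.188 (0.137 to 0.254) and 0.263 (0.187 to 0.362). Among 20 genes of DNA replication 7 were lower and 2 higher, with the thymidylate synthase gene Tyms at a ratio of 0.195 and 0.0760 and the helicase subunit Mcm2 at 0.149 (0.0981 to 0.220) and 0.157 (0.0939 to 0.248). Among 15 genes of division 5 were lower and 2 higher, with Aurkb at 0.116 and 0.0910 and Incenp at 0.351 and 0.431. In the list of let-7 and miR-202 seed-family targets 5 of 37 were lower and 3 higher. Trim71 was at 0.00689 and, from 0 UMIs set at the floor of 3 counts, 0.0279 (interval up to 0.0346). The cyclin gene Ccnd1 was at 0.110 (0.0731 to 0.160) and 0.140 (0.0899 to 0.208). Of 5 self-renewal genes 2 were lower and 1 higher. Foxo1 was at a ratio of 0.214 and 0.266, and Pou3f1 stood at 84.4 and 72.8 CPM in spermatogonium-like cells and at 0 UMIs in early spermatocyte-like cells. With the floor of 3 counts its ratio was 0.0222 and 0.0320, with intervals up to 0.0275 and 0.0398.

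Over the 23 lists, 39 of 320 measured genes were higher and 31 lower in early spermatocyte-like than in spermatogonium-like cells by the size rule. The median ratio of genes with at least 50 UMIs in both classes lay at 0.22 and 0.19 on the log2 scale under marks 1 and 2. Scaled by it, the split was 30 higher and 38 lower. Free RNA was estimated at 45.1% and 52.2% of UMIs in spermatogonium-like cells and at 51.4% and 66.7% in early spermatocyte-like cells, or at 37.0% and 41.2%, and 42.1% and 52.6%, from the 2 clusters alone. These shares may be too high, since barcodes rich in protamine UMIs raise the mean of Prm1, Prm2, Tnp1 and Tnp2 UMIs to 369 per spermatogonium-like barcode against a median of 210.5. With the listed genes left out of the clustering 4 recombination genes were higher, Msh5 not among them, pachytene and XY body regulators were higher in 4 cases and lower in 2, and 8 seed-family targets were lower, against 11 with free RNA subtracted. That clustering also moved flagellum genes from 1 to 11 higher, acrosome genes from 0 to 3 and sperm chromatin genes from 3 to 6, so these calls depend on it. For the mixed class against early spermatocyte-like cells it left flagellum genes at 11 higher and acrosome genes at 3 higher. The first naming rule gave 59 listed genes higher and 56 lower.

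In the mixed spermatocyte-like class, genes of the flagellum and genes tied to translational delay were more often higher than lower against early spermatocyte-like cells. Regulators of pachytene and the XY body and genes of the miRNA machinery were more often lower. Genes of the whole table leaned the same way, with 1533 lower and 1289 higher. The median of the miRNA machinery list lay at percentiles 5.86 and 11.1, within the range of random lists. That of the pachytene and XY body list lay at percentiles 0.72 and 0.12. Of 22 flagellum genes 11 were higher and 5 lower, 14 and 4 with either scaling, and 17 and 1 with free RNA subtracted. The axonemal dynein genes Dnah8 (5.63-fold, 5.09 to 6.25, and 4.31-fold, 3.85 to 4.84) and Dnah1 (4.48-fold and 4.88-fold) were higher, and Akap3, an anchor protein of the fibrous sheath, was lower at a ratio of 0.248 and 0.270. Of 19 genes tied to translational delay in spermatids 10 were higher and 3 lower, and 11 and 5 with free RNA subtracted. The piRNA pathway list, which shares members with it, held 6 higher and 1 lower of 19, 11 higher with TMM factors, and 7 higher and 5 lower with free RNA subtracted. Tdrd1 was 5.35-fold (4.13 to 7.06) and 5.78-fold (4.34 to 7.88) higher and Pld6 6.36-fold and 4.23-fold, while the RNA-binding protein gene Dazl fell from 1056 and 993 CPM to 94.1 and 160 CPM and Cpeb1 was at a ratio of 0.0496 and 0.101. Of 17 genes of glycolysis 5 were higher and 4 lower: the glucose transporter gene Slc2a3 was 5.34-fold and 4.35-fold higher and Ldha 3.90-fold and 3.41-fold, and Pkm was lower at a ratio of 0.173 and 0.290.

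Of 20 cohesin genes 6 were lower in the mixed class and 1 higher, and 4 and 3 with TMM factors: Smc3 was at a ratio of 0.0419 (0.0367 to 0.0477) and 0.0666 (0.0579 to 0.0765), Esco2, which acetylates it, at 0.0566 and 0.0636, and the securin gene Pttg1 was 2.998-fold and 2.83-fold higher. Of 6 measured genes of the synaptonemal complex 3 were lower, 2 of them with TMM factors, and 1 higher, with 4930447C04Rik at 0.118 and 0.173 and the central element gene Syce2 at 0.177 (0.162 to 0.194) and 0.233 (0.212 to 0.256). Of 20 genes of DNA replication 6 were lower and 1 higher, with Mcm5 at 0.0551 and 0.112 and Rrm2 at 0.105 and 0.0743. With the listed genes left out of the clustering 2 were lower, and with either scaling 3 were higher. Recombination genes were lower in 6 of 24 cases and higher in 4, and 4 and 4 with that clustering, with X-linked Tex11 at 0.00679 and 0.00391 and Brip1 at 0.0272 and 0.0294. Of 14 regulators of pachytene and the XY body 5 were lower, 9 with free RNA subtracted and 10 with the profile of 2 clusters, including X-linked Scml2 (0.00415 and 0.00636) and Y-linked Uba1y (0.0123 and 0.0202). Of 17 genes of the miRNA machinery 5 were lower, 7 with free RNA subtracted, and 1 higher, and 4 and 2 with TMM factors. The nuclease gene Dicer1 was at 0.0338 (0.0243 to 0.0464) and 0.0534 (0.0393 to 0.0723), and Tnrc6b, a scaffold of silencing complexes, at 0.0329 and 0.0545. In the list of let-7 and miR-202 seed-family targets, which also holds Dicer1 and Cpeb1, 9 of 35 were lower and 1 higher, and 6 and 3 with TMM factors.

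Across all lists 45 of 310 genes were higher and 79 lower in the mixed class. Relative to the median ratio, at −0.35 and −0.27 on the log2 scale, the split was 61 higher and 70 lower, and with TMM factors it was 70 higher and 57 lower. Of 10 sperm chromatin genes 8 were lower, with Hist1h2aa at 0.0674 and 0.156, H2al2a at 0.238 and 0.276 and H1fnt at 0.245 and 0.280, but 2 were lower once the free-RNA profile had been subtracted, and the estimated free share was 51.4% and 66.7% in early spermatocyte-like cells against 13.4% and 19.7% in the mixed class. The mitochondrially encoded genes were lower in 11 of 13 cases, with mt-Nd4l at 0.263 and 0.349 and mt-Atp8 at 0.285 and 0.415, and in 5 with TMM factors.

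Late spermatocyte-like cells had more transcript of some genes that drive the meiotic divisions than the mixed class, and less of some piRNA, mitochondrial and pachytene genes. Of 14 division genes 5 were higher and 0 lower. Cyclin B1 (Ccnb1) was 9.27-fold (8.49 to 10.1) and 7.99-fold (7.29 to 8.76) higher, rising from 32.9 and 39.5 CPM to 305 and 316 CPM, the polo kinase gene Plk1 was 5.48-fold and 6.16-fold higher and Cdk1 1.74-fold and 2.08-fold. Of 22 flagellum genes 5 were higher and 0 lower, with the tektin genes Tekt4 at 3.96-fold and 3.78-fold and Tekt3 at 2.09-fold and 2.80-fold. In the let-7 and miR-202 seed-family list, Cdc25a, a phosphatase that activates cyclin-dependent kinases, and Nr6a1 were higher, the former at 4.53-fold and 5.49-fold.

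Of 19 piRNA genes 9 were lower in late spermatocyte-like cells and 0 higher, with Tdrd5 at a ratio of 0.131 (0.109 to 0.156) and 0.123 (0.1001 to 0.1504), Tdrd1 at 0.170 and 0.132 and Piwil2 at 0.230 and 0.183. Mitochondrially encoded genes were lower in 9 of 13 cases, with mt-Cytb at 0.213 (0.204 to 0.222) and 0.149 (0.142 to 0.157) and mt-Nd3 at 0.315 and 0.235. Of 14 regulators of pachytene and the XY body 6 were lower, including Mdc1 (0.385 and 0.327) and, from the same checkpoint pathway, Topbp1 (0.107 and 0.0773) and Atr (0.442 and 0.407). Recombination genes were lower in 3 of 23 cases, among them Brca2 at 0.321 and 0.344 and Ankrd31 at 0.354 and 0.357, and higher in 1. Over the lists 17 of 298 genes were higher and 38 lower, and scaling by the median ratio or by TMM factors (−0.01 and −0.16 on the log2 scale) gave the same counts. Without the filter on CPM, and with the UMI minimum lowered from 50 to 20, 117 were lower.

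Round spermatid-like cells had more transcript of some acrosome and sperm chromatin genes than late spermatocyte-like cells, and less of some division and mitochondrial genes. Of 8 acrosome genes 5 were higher: the hyaluronidase gene Spam1 was 14.7-fold (11.8 to 18.6) and 26.1-fold (18.5 to 37.9) higher, Eqtn 11.4-fold and 13.5-fold, and Spaca4 8.81-fold and 12.6-fold. Dpy19l2 and Zpbp2 were lower, the former at a ratio of 0.578 and 0.628, and neither passed after scaling by the median ratio. Of 11 sperm chromatin genes 6 were higher and 0 lower, with the spermatid linker histone gene Hils1 at 5.999-fold (5.71 to 6.31) and 7.27-fold (6.81 to 7.77) and the remodeller gene Chd5 at 6.55-fold and 8.59-fold, and 3 were higher once the free-RNA profile had been subtracted. Of 17 genes of glycolysis 5 were higher and 1 lower. Aldoart2 and Aldoart1, close copies of Aldoa between which the counting could have split reads, were 6.09-fold and 7.86-fold and 4.17-fold and 5.29-fold higher, and Slc2a3 was lower at 0.158 and 0.149.

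Of 14 division genes 7 were lower in round spermatid-like cells and 1 higher, with Cdk1 at a ratio of 0.150 (0.137 to 0.164) and 0.137 (0.126 to 0.148) Incenp at 0.337 and 0.364, and Cdc20, which activates the anaphase-promoting complex, at 0.359 and 0.342. Cohesin genes were lower in 6 of 19 cases, and in 3 relative to the median ratio, and higher in 1. The cohesin protector gene Sgo2a was at 0.150 and 0.135 and Espl1 at 0.329 (0.289 to 0.374) and 0.299 (0.262 to 0.343), while Smc3 was 2.76-fold and 3.51-fold higher. Mitochondrially encoded genes were lower in 8 of 13 cases, with mt-Nd1 at 0.208 and 0.234 and mt-Nd2 at 0.262 and 0.314. Of 19 piRNA genes 3 were lower, 1 of them relative to that median, and 2 higher, with Pld6 at 0.361 and 0.326, Tdrd12 at 0.511 and 0.494 and Gtsf1 at 1.76-fold and 1.79-fold. The lists held 30 higher and 51 lower genes of 305, and 36 higher and 36 lower relative to the median ratio, which lay at −0.41 and −0.44 on the log2 scale.

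Elongating spermatid-like cells had less transcript of acrosome genes than round spermatid-like cells, and more of some sperm chromatin genes. The kinase gene Tssk6 was 10.79-fold (10.55 to 11.05) and 10.97-fold (10.75 to 11.21) higher, the histone variant gene H2al2a, a member of a family of close copies, 9.44-fold and 10.8-fold, and H1fnt 4.84-fold and 5.99-fold. In all 4 of 11 sperm chromatin genes were higher and 1, Brdt, was lower, though not relative to the median ratio, where 7 were higher. With TMM factors 6 were higher and 1 lower. Of 17 genes of glycolysis 3 were higher and 4 lower: Pkm stood at 36.6 and 34.4 CPM in round spermatid-like cells and at 202 and 207 CPM in elongating spermatid-like cells, Eno4 at a ratio of 0.253 and 0.258 and Ldha at 0.274 and 0.262. With scaling by the median ratio 8 were higher and 3 lower.

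Of 8 acrosome genes 8 were lower, with Spam1 at a ratio of 0.124 (0.115 to 0.134) and 0.131 (0.122 to 0.140) and Zp3r at 0.149 and 0.148. Flagellum genes were lower in 16 of 22 cases and higher in 2, with Fsip2 at 0.153 and 0.157 and Tekt2 at 0.159 and 0.152, and genes tied to translational delay in 11 of 19 cases, with Tdrd7 at 0.186 and 0.180, Ddx4 at 0.232 and 0.222 and the poly(A)-binding protein gene Pabpc1 at 0.233 and 0.234. The medians of the flagellum list (5.84 and 12.7) and the translational delay list (12.8 and 9.01) lay at percentiles within the range of random lists. The median ratio lay at −1.12 and −1.15 on the log2 scale, so most genes with at least 50 UMIs in both classes were lower on the CPM scale. Relative to it 28 listed genes were higher and 41 lower, and 23 and 43 with TMM factors, against 13 higher and 74 lower of 315 by CPM, flagellum genes were lower in 9 cases and higher in 4, translational delay genes lower in 7 and higher in 1, and mitochondrially encoded genes lower in 0 cases against 5 and higher in 2 against 0. With free RNA subtracted the number of lower mitochondrially encoded genes was 0, or 8 from the 2 clusters alone.

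Lists for somatic functions, stress and cell death held few genes past the rule in any step, which does not mean that they stayed level. From spermatogonium-like to early spermatocyte-like cells the dissociation and heat stress list had a median log2 ratio of −1.27 and −1.03. These lay at percentiles 0.205 and 0.84 of random lists. For p53 response and apoptosis it was −1.10 and −0.460, at percentiles 0.04 and 2.57. From round to elongating spermatid-like cells both lists lay high, at percentiles 94.9 and 96.1, and 89.8 and 98.2. Steroidogenesis genes passed in none, and of the Sertoli function genes Tjp1 was lower in the mixed class than in early spermatocyte-like cells, at a ratio of 0.402 and 0.333. Of the dissociation and heat stress genes Dnajb1 was higher in late spermatocyte-like cells than in the mixed class (1.73-fold and 2.15-fold) and lower in elongating than in round spermatid-like cells. The latter call was lost with scaling by the median ratio and with TMM factors. In the list of p53 response and apoptosis, 1 of 23 genes was higher and 1 lower in early spermatocyte-like than in spermatogonium-like cells, Diablo at 1.72-fold and 1.98-fold and Bax at a ratio of 0.231 and 0.216. In the mixed class 2 of 25 were higher than in early spermatocyte-like cells, Diablo (1.98-fold and 1.95-fold) and Bcl2l1 (1.80-fold and 1.59-fold), and Cycs was lower, at 0.0822 and 0.0907. In the list of spermatogonial differentiation, X-linked Sox3 (0.153 and 0.124) and Uhrf1 were lower in early spermatocyte-like than in spermatogonium-like cells.

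Somatic classes held their own marker transcripts beside spermatid RNA. Leydig cell-like cells held Cyp17a1, an enzyme of androgen synthesis, at 2462 (2335 to 2595) and 2202 (2078 to 2331) CPM, against 1.18 and 2.34 CPM in Sertoli cell-like cells. Sertoli cell-like cells held Cst9 at 696 and 726 CPM, and macrophage-like cells held the complement gene C1qa at 1943 and 1909 CPM. Prm1, a protamine gene of late spermatids, stood at 77542 and 77761 CPM in elongating spermatid-like cells, and at 22317 and 21162 CPM in T or NK cell-like cells and 19232 and 21463 CPM in Leydig cell-like cells, which should lack it. The median sum of Prm1, Prm2, Tnp1 and Tnp2 UMIs per barcode was 205 over T or NK, macrophage and Leydig cell-like barcodes, 210.5 in spermatogonium-like, 240 in round spermatid-like and 1770 in elongating spermatid-like barcodes.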

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

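All tests in this part were chosen after the results had been seen. The design gives no group that applies to these patterns, so no biological explanation was tested.

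The 6 unnamed clusters of low UMI count, with 12456 barcodes, held 854693 UMIs of 22 late spermatocyte markers, 505329 of them from Ldhc, a signal outside the classes compared. Free RNA may supply their protamine and transition protein UMIs: the median of Prm1, Prm2, Tnp1 and Tnp2 UMIs per barcode lay outside 1.5-fold of the 205 found in somatic barcodes in 0 of the 6 clusters. Whether free RNA is all they hold stays open. In the cluster led by Pou5f2 the markers other than Pou5f2 were counted per protamine and transition protein UMI. Without protamine-rich barcodes they stood at 1.343 (1.31 to 1.37) and 1.27 times the somatic ratio under marks 1 and 2. Without Ldhc too they stood at 1.26 and 1.17, and all these values lay below the bound of 1.5. Medians per barcode, with protamine-rich barcodes kept, stood above it, at 1.51 and 1.58 times the somatic median. Summed over all barcodes the markers stood at 2.24 and 2.12, but protamine-rich somatic barcodes, at a mean of 383 UMIs against a median of 205, lower the somatic ratio. The other 5 clusters reached 1.2045 without protamine-rich barcodes. Those led by Gm8251 (0.770 and 0.647), Ttn (0.971 and 0.824) and AY036118 (0.920 and 0.816) lay below the somatic ratio. Free RNA alone predicts that ratio within counting error, which was met only in the cluster led by mt-Nd2 under mark 1 (0.995 to 1.040). The spread between barcodes is not in these intervals. In the cluster led by Gm35256, Piwil1 (1.99 and 2.81) and Spata16 (2.19 and 2.20) lay above 1.5. Spag6 (0.734 and 0.558) and Pgk2 (0.834 and 0.827) lay below 1 there. In the cluster led by mt-Nd2 Spag6 (0.796 and 0.531) and Pgk2 (0.859 and 0.821) also lay below 1, so low values of these 2 are not particular to it. Aym1 stood at 51.4 (17.4 to 250) over all barcodes in the cluster led by Gm35256, from 3 somatic UMIs. These values rest on few of 18 markers, picked after they were seen, and cannot decide whether that cluster holds free RNA alone. Damage to cells may also contribute and stays open: the clusters led by Pou5f2, Gm8251 and AY036118 had medians of up to 0.177% mitochondrial UMIs, a value between those of elongating (0.0736% and 0.0544%) and round spermatid-like barcodes (0.231% and 0.254%). The cluster led by Ttn had at least 4.17%, near the 4.42% and 4.44% of spermatogonium-like barcodes, and those led by mt-Nd2 and Gm35256 at least 5.46% and up to 11.03%, above every named class, but mitochondrial genes are among those that lead these 3 clusters, so this share cannot decide.

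The unnamed cluster led by AY036118 and other ribosomal-repeat genes held 7007 haemoglobin UMIs, although it was not named erythroid. Free RNA spread over its barcodes is argued against, since 97.1% of these UMIs lay in barcodes with at least 100 of them, 8 barcodes in number. Barcodes with any haemoglobin UMI made up 5.47% of the cluster (4.54 to 6.53%) and 5.32% of round spermatid-like barcodes. The pattern was not particular to this cluster. The other low-UMI unnamed clusters held 11484 haemoglobin UMIs, 95.1% of them in 8 barcodes. Round spermatid-like barcodes held 3472, 92.1% of them in 3 barcodes. Whether such barcodes hold erythroid cells joined to others was not tested.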

How the results depend on the processing

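Alternatives for 1 doublet threshold, the listed genes left out, the first naming rule, the low-UMI cluster and free RNA (from 6 or 2 clusters) were chosen after seeing the data. Of the class shares under the alternatives 73 stayed within their binomial interval and 46 moved, and of the counts of listed genes 110 stayed within 1.5 times and 26 moved. The balance of higher and lower turned for mixed against early spermatocyte-like cells, from 45 and 79 to 70 and 57 with TMM factors. It turned for early spermatocyte-like against spermatogonium-like cells, from 39 and 31 to 30 and 38 with the median ratio. With no CPM filter and at least 20 UMIs in place of 50 it was 57 and 64, and it was even (33 and 33) at resolution 2. For round against late it turned from 30 and 51 to 29 and 17 with thinned cells, and was even (36 and 36) with the median ratio. No paired analysis was possible because the genotypes share only replicate number 1 and no barcode mark is tied to a genotype. The seed-site and genotype comparisons, with their alternatives, were not run. Keeping every barcode changed nothing, since the filter removed none.

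Shares moved as follows, and the cause was not tested. At resolution 0.5 the spermatogonium-like share was 0.736%, mixed 3.43%, late 0, round 13.4% and unnamed 51.2%. At resolution 2 the spermatogonium-like share was 1.56%, early 1.83%, mixed 2.04%, late 2.63%, round 10.8%, elongating 26.0% and unnamed 49.1%. With 15 components they were 0.995% for spermatogonium-like, 1.88% for early, 3.16% for mixed, 25.2% for elongating, 0.177% for macrophage, 0 for T or NK, 5.86% for erythroid and 39.9% for unnamed. The stricter filter gave 0.806% spermatogonium-like, 3.23% mixed, 20.6% round, 25.9% elongating and 40.6% unnamed. Without called doublets the spermatogonium-like share was 0.772%, elongating 24.6% and unnamed 46.8%. With 1 doublet threshold the spermatogonium-like share was 1.31%, round 17.9%, elongating 25.1% and unnamed 44.0%. Centring within a library gave 17.0% round, 24.6% elongating and 45.2% unnamed. Without the listed genes the spermatogonium-like share was 0.818%, early 1.78%, round 9.97% and unnamed 53.1%. The first naming rule gave 1.57% spermatogonium-like, 2.30% early, 3.31% late, 10.4% round, 0.407% macrophage, 1.25% erythroid and 50.5% unnamed, and no mixed class.

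Without the 5 top X-linked genes the X-linked share was 1.42% in spermatogonium-like, 1.41% in early, 0.118% in mixed, 0.193% in late, 0.822% in round, 0.937% in elongating, 1.21% in Sertoli and 1.43% in Leydig cell-like cells, which is lower by construction.

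Counts of listed genes moved most with filters that act by construction. The setting named no CPM filter below also lowered the UMI minimum from 50 to 20. For early spermatocyte-like against spermatogonium-like cells a ratio of 2 gave 24 higher and 19 lower, thinned cells 3 and 1, no CPM filter 57 and 64, and the first rule 59 and 56. For mixed against early, a ratio of 2 gave 26 higher, thinned cells 29 and 15, and no CPM filter 125 lower. For late against mixed, no CPM filter gave 28 and 117, a ratio of 2 gave 6 higher, and thinned cells 9 and 24. For round against late, no CPM filter gave 77 and 98 and thinned cells 29 and 17. For elongating against round, the median ratio gave 28 and 41, TMM factors 23 and 43, and no CPM filter 28 and 197. The causes under TMM, the median ratio and the first rule were not tested. Single listed genes took the opposite call in 2 cases under the first naming rule (Taf4b and Tdrd1), in 1 with free RNA subtracted, from 6 or from 2 clusters (Tekt4) and in 1 at resolution 2 (Tekt5). Depth limits genes below 50 CPM, which the rule cannot call.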

Other observations

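In this part the test of Igkc was planned before its result was seen, and the genes under each mark were singled out after their values were seen.

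Single genes of further lists also passed the size rule. In early spermatocyte-like cells the terminal uridylyltransferase gene Tut7 was 2.61-fold and 2.50-fold higher than in spermatogonium-like cells, while 2 other genes of the miRNA machinery, Tnrc6a and Drosha, were lower, and the glycolytic gene Gapdh, which has many pseudogene copies, was lower at a ratio of 0.187 and 0.1995. Tut4 was lower in the mixed class than in early spermatocyte-like cells, at 0.293 and 0.312, while Tarbp2, a partner of Dicer, was 2.30-fold and 1.98-fold higher there and lower again in round spermatid-like cells, at 0.422 and 0.421. In elongating spermatid-like cells Cdc34 was 4.604-fold and 4.68-fold higher than in round spermatid-like cells, from a list with 2 higher and 4 lower, and Bcl2l11, a gene of apoptosis, 3.48-fold and 4.49-fold higher, whereas Mdm2 was lower at 0.198 and 0.203.

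Summed over all barcodes, 3 genes passed the size rule between the marks, and all 3 had the larger value under mark 1. Igkc stood at 62.6 CPM and at 0 UMIs, Tmem242 at 55.0 and 26.3 CPM, and Hemgn at 95.8 and 63.3 CPM. Hemgn was among the leading genes of the unnamed cluster of 482 and 281 barcodes, which held 3.73% and 1.84% of barcodes under the marks. It was also among those of the cluster led by AY036118, at 7.40% and 7.59%. Whether its value follows the size of the former cluster was not tested. That a few barcodes hold the Igkc UMIs is a candidate explanation of its value: 96.7% lay in barcodes with at least 100 of them, 4 of 12935 barcodes, with up to 4821 in 1 barcode. Gm2044, a long noncoding RNA gene that overlaps Mir202 on the same strand (chromosome 7, 139957005 to 139958039, GRCm38), had 379 UMIs under mark 1 and 61 under mark 2, with 50.9 and 10.4 CPM in Sertoli cell-like cells. In Leydig cell-like cells it stood at 87.8 CPM (65.2 to 116), from 50 UMIs, under mark 1 and at 0 UMIs under mark 2, where the exact interval reaches 6.84 CPM. These values were not used to assign a genotype to a mark, and no genotype is read from them.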
